A study of Homo sapiens with 8 samples.

How the data were processed

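Gene expression was measured in SJRH30, an established human cell line of alveolar rhabdomyosarcoma, a childhood tumour of the skeletal muscle lineage. Cells were collected before hypoxia (0 h) and after 6, 12 and 24 h in a chamber held at 1% oxygen, with 2 replicates per time that the labels call biological, giving 8 arrays. Per the labels' protocols, 10 µg of total RNA, extracted with a silica column kit, was converted to biotin-labelled RNA in a single round of amplification and hybridised to a 3′-based Affymetrix array. No cells kept in normal oxygen for 6, 12 or 24 h were analysed here, so time in culture and time in hypoxia run together in every comparison.

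The deposited values are log2 probe set summaries made by the authors with RMA, per the submitters' processing notes; the RMA version and software are not given in the sources used here. In its usual form RMA subtracts background, makes the distribution of probe values equal between arrays and summarises each probe set on the log2 scale. This removes any difference in total messenger RNA between arrays, so every change reported is relative to the other transcripts of the same array. The table held 22277 probe sets with values from 2.72 to 14.5, and the median of all probe sets lay between 6.69 and 6.73 on every array. Depth has no meaning for an array; the number of arrays limits the precision. The median absolute difference between the 2 replicates of a time was 0.06 at 0 h, 0.07 at 6 h, 0.07 at 12 h and 0.10 at 24 h on the log2 scale.

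Probe sets were named from the platform annotation of 2016. It listed 20113 of them, of which 19070 had 1 gene symbol and 1043 had several. A further 2164 were not listed and are unnamed here, and 2108 of these are not control probe sets. Symbols were checked through Entrez identifiers, of which 19052 matched a RefSeq gene table of assembly GRCh38.p14, used for names alone. The 62 control probe sets were kept apart. Each gene was represented by the probe set with the highest mean over all arrays among those with that symbol alone, which gave 11963 genes, 4310 of them with several probe sets to choose from. No filter on dim probe sets was applied. Low signals on such arrays contain cross-hybridisation, which shrinks the changes of dim genes.

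Group means of the 4 times were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), leaving 4 residual degrees of freedom per gene, to which the empirical Bayes prior added 3.68. The 3 hypoxic times were each compared with 0 h and with each other, and a moderated F-test covered the 3 comparisons with 0 h. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a comparison over all genes, and a gene was called at an adjusted p under 0.05. Fold changes are given on the log2 scale with the standard error of the fit. All 32 gene lists, holding 621 genes of which 542 were measured, were written before the data were examined. They cover the hypoxia response, metabolism, the cell cycle, stress pathways, muscle and tumour identity, markers of other cell types and reference genes. Some core targets of the hypoxia-inducible factors were also in other lists. BNIP3 and BNIP3L were in autophagy, EGLN1, EGLN3 and CITED2 in oxygen sensing, KDM3A and KDM4B in demethylases and INSIG2 in cholesterol synthesis. VEGFA, ADM and ANGPTL4 were in angiogenic factors. Calls of these lists are therefore not independent of the core target list. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the 4 residual degrees of freedom and with fry. The estimated form also bases its p-values on these 4 degrees of freedom. A call lost with it therefore does not by itself show correlation between the members of a list. Counts of called members are given over all genes and, in separate words, adjusted over the list alone.

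The genes named in the text were set by a rule fixed before the data were examined. They are the 8 largest rises and 8 largest falls among called genes in each comparison with 0 h, and 5 of each between hypoxic times, all with replicates that did not overlap between the times. To these were added up to 4 called members of each list described (2 of the uncalled where none was called) and 27 fixed genes, of which CA9, ANKRD37 and IGF2 were not analysed here. Exceptions are marked where they occur.

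The procedure was tested on simulated data shaped like the comparison of 6 h with 0 h, with 200 of 11963 genes changed in 20 simulations. It recovered 74.5% of genes changed by 0.5 on the log2 scale, 97.5% of those changed by 1 and 99.9% of those changed by 2, and 4.96% of its calls were false. A changed list, with all members raised by 0.5, was called in 20 of 20 simulations and an unchanged list in 0. These calls were at an unadjusted camera p under 0.05. Genes varied independently in the simulations, so they did not test the preset correlation on lists of correlated genes. Alternatives tried were the mean of all probe sets of a gene, each probe set tested separately, leaving out dim genes, further quantile normalization, centring of each array, an intensity trend in the variance, fits of only the groups compared, a replicate block, leaving out each array in turn, and other thresholds. Leaving out both 12 h arrays and a block with the 12 h numbers crossed were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.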

Results

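The series follows the transcriptome of SJRH30 cells, an alveolar rhabdomyosarcoma line, through 24 h in 1% oxygen. It holds 4 times (0, 6, 12 and 24 h) with 2 arrays each, and the question its design poses is which genes respond to hypoxia at each time. Expression of 11963 genes was compared. Replicate arrays correlated at 0.997 or higher across genes, which are not independent replicates. Correlations between arrays of different times were close to this, from 0.993 to 0.998. The 12 h replicates, at 0.9975, were no closer than 12 h replicate 1 and 6 h replicate 2, at 0.9980. The moderated F-test over the time course called 1940 genes, or 16.2%. It called 397 and 374 without 0 h replicate 1 or 2, 943 and 1063 without 6 h replicate 1 or 2, and 3333 with an intensity trend in the variance.

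**Figure D1:**
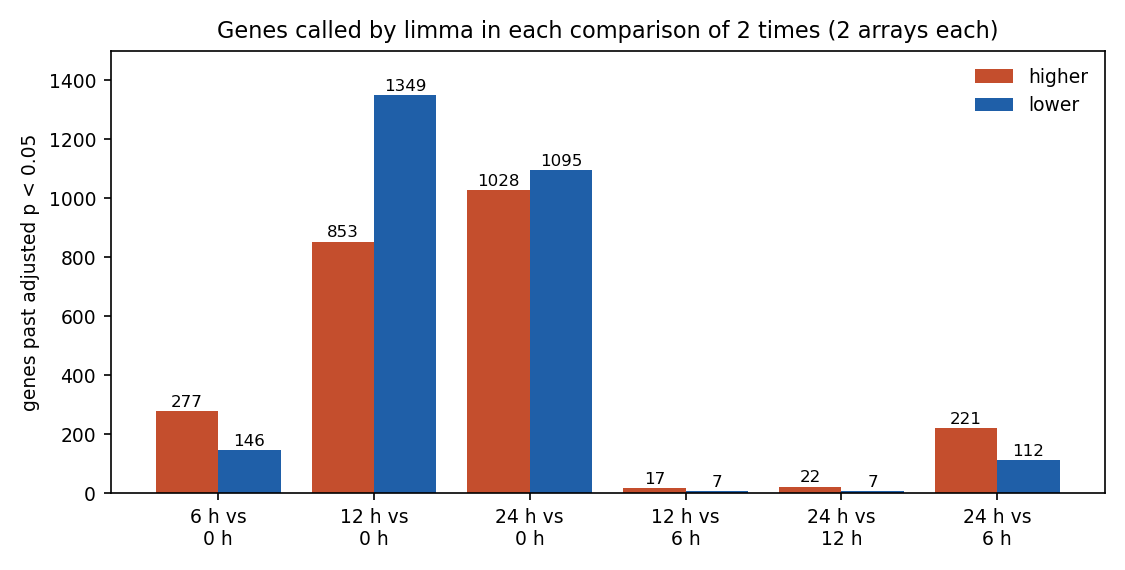
Number of genes called higher (red) and lower (blue) by limma in each comparison between times, 2 arrays per time, at an adjusted p under 0.05. The comparisons with 0 h gave 423 genes at 6 h, 2202 at 12 h and 2123 at 24 h, against 24, 29 and 333 between hypoxic times.

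After 6 h the largest rises were in genes of the hypoxia response and of sugar metabolism. BNIP3, which encodes a mitophagy receptor, rose 7.78-fold, from 9.28 ± 0.09 to 12.24 ± 0.03 on the log2 scale (SD, n = 2; log2 change 2.96 ± 0.07 SE, adjusted p = 1.56e-06). DDIT4, an inhibitor of mTORC1 signalling, rose by 2.34 ± 0.07 (adjusted p = 4.37e-06) and TMEM45A by 2.05 ± 0.05. The glucose transporter gene SLC2A1 rose 3.998-fold. The angiogenic factor VEGFA rose by 1.90 ± 0.09, and the metabolic kinase genes PDK1, PFKFB3 and HK2 by 2.05, 1.91 and 1.87. Falls were smaller. The largest were in WDR5B (-0.84 ± 0.17, adjusted p = 0.038), the heme oxygenase gene HMOX1 (-0.74 ± 0.06), the pro-apoptotic gene PMAIP1 (-0.72) and ANXA1 (-0.71). ELL2 (-0.69), the transcription factor gene EGR1 (-0.68), the growth factor gene HBEGF (-0.68) and the small heat shock gene HSPB8 (-0.66) followed. In all, 277 genes were higher and 146 lower, 30 of the rises were 2-fold or more, and the largest fall was 1.79-fold. Without 0 h replicate 1 or 2 the count of 423 became 92 or 111, and without 6 h replicate 1 or 2 it became 90 or 131, the lone array being assumed to vary like the other groups. An intensity trend in the variance raised the count to 1206, with a more even balance of 670 higher and 536 lower. Without the dimmer 50% of genes 698 were higher and 625 lower.

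Of 27 measured core targets of the hypoxia-inducible factors (HIF), 22 rose and 0 fell at 6 h, with a median change of 0.98 (camera adjusted p = 2.44e-41; adjusted p = 0.0314 with an estimated correlation; 22 and 0 adjusted over the list alone). In glycolysis 11 of 22 genes rose and 0 fell (adjusted p = 1.39e-21, 0.0318 with an estimated correlation), or 17 adjusted over the list alone. Among collagen modification and matrix genes 5 of 18 rose, or 9 adjusted over the list alone, led by the lysyl hydroxylase gene PLOD2 (1.72), the prolyl hydroxylase subunit gene P4HA1 (1.45), PLOD1 (0.74) and COL3A1 (0.34) (adjusted p = 1.78e-08, 0.0318 with an estimated correlation). Mitosis genes also rose as a group, 8 of 30, or 14 adjusted over the list alone, with HMMR at 0.45 and ASPM at 0.40 (adjusted p = 3.14e-11, 0.0318 with an estimated correlation). These were the 4 lists called with both correlations.

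The other calls at 6 h were lost with an estimated correlation. Among them, DNA repair genes were called higher (camera adjusted p = 0.00629, 0.329 with an estimated correlation). MYC targets and ribosome biogenesis genes were called lower (camera adjusted p = 0.0262, 0.332 with an estimated correlation). Oxygen-dependent histone and DNA demethylase genes rose in 6 of 13, or 7 adjusted over the list alone, with 1 lower there, led by KDM3A at 1.47 and TET1 at 1.12 (adjusted p = 1.14e-05, but adjusted p = 0.107 with an estimated correlation). In cholesterol and fatty acid synthesis 4 of 18 genes rose, with the sterol regulators INSIG2 at 1.65 and INSIG1 at 0.47 (adjusted p = 0.00174; adjusted p = 0.0944 with an estimated correlation; 4 adjusted over the list alone). Among genes associated with the PAX3-FOXO1 fusion protein 3 of 23 rose, ALK by 0.77, PDGFRA by 0.67 and IGF1R by 0.32, or 9 adjusted over the list alone (adjusted p = 0.00118; adjusted p = 0.107 with an estimated correlation). Among unfolded protein response and ATF4 genes 7 of 23 fell and 2 rose, or 10 and 3 adjusted over the list alone. DDIT3 fell by 0.63, TRIB3 by 0.57 and ASNS by 0.54, while VLDLR rose by 1.39 (adjusted p = 0.00174; adjusted p = 0.156 with an estimated correlation). Immediate early genes fell in 3 of 20, or 6 adjusted over the list alone, EGR1 by 0.68, ATF3 by 0.46 and MYC by 0.31 (adjusted p = 0.00174; adjusted p = 0.0944 with an estimated correlation). NF-kB genes fell in 2 of 16, CXCL2 by 0.52 and IRF1 by 0.37, or 7 lower and 1 higher adjusted over the list alone (adjusted p = 0.00174; adjusted p = 0.0944 with an estimated correlation).

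On the arrays of all hypoxic times the control probe sets moved too. The mean of 24 probe sets for poly-A RNA added during preparation was higher than at 0 h by 0.47 at 6 h, 0.43 at 12 h and 0.65 at 24 h, and that of 18 probe sets for hybridisation controls by 0.25, 0.19 and 0.19. A 5′ probe set of 28S ribosomal RNA fell by 0.60, 0.95 and 1.01 (limma adjusted p = 0.00495, 0.000245 and 0.000141). A 5′ probe set of 18S ribosomal RNA was at -0.08, -0.09 and 0.03. Only these 5′ probe sets of the ribosomal RNAs were read. The 3′ minus 5′ values of GAPDH, a sign of RNA integrity, were -0.10, -0.10, -0.05 and -0.05 at 0, 6, 12 and 24 h, and those of ACTB 0.02, 0.07, 0.10 and 0.11.

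**Figure D2:**
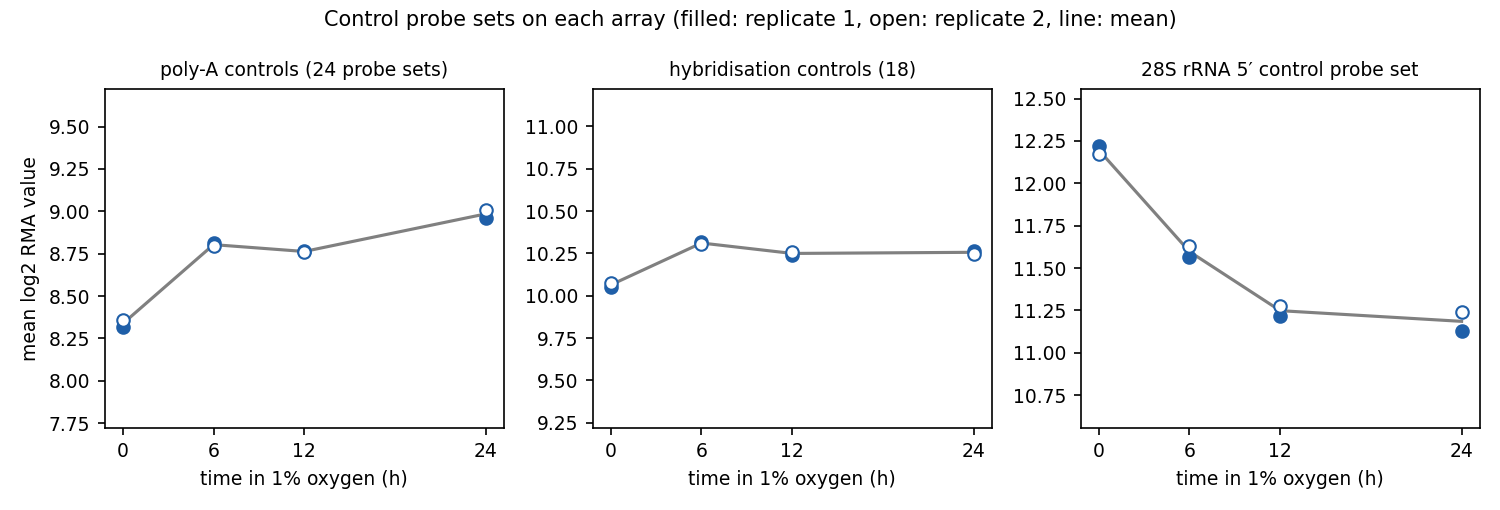
Mean log2 RMA value of 24 poly-A control probe sets, 18 hybridisation control probe sets and a 28S ribosomal RNA probe set on each array against hours in 1% oxygen (filled points replicate 1, open points replicate 2, lines the mean). From 0 to 24 h the poly-A controls changed by 0.65, the hybridisation controls by 0.19 and the 28S probe set by -1.01.

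**Figure D3:**
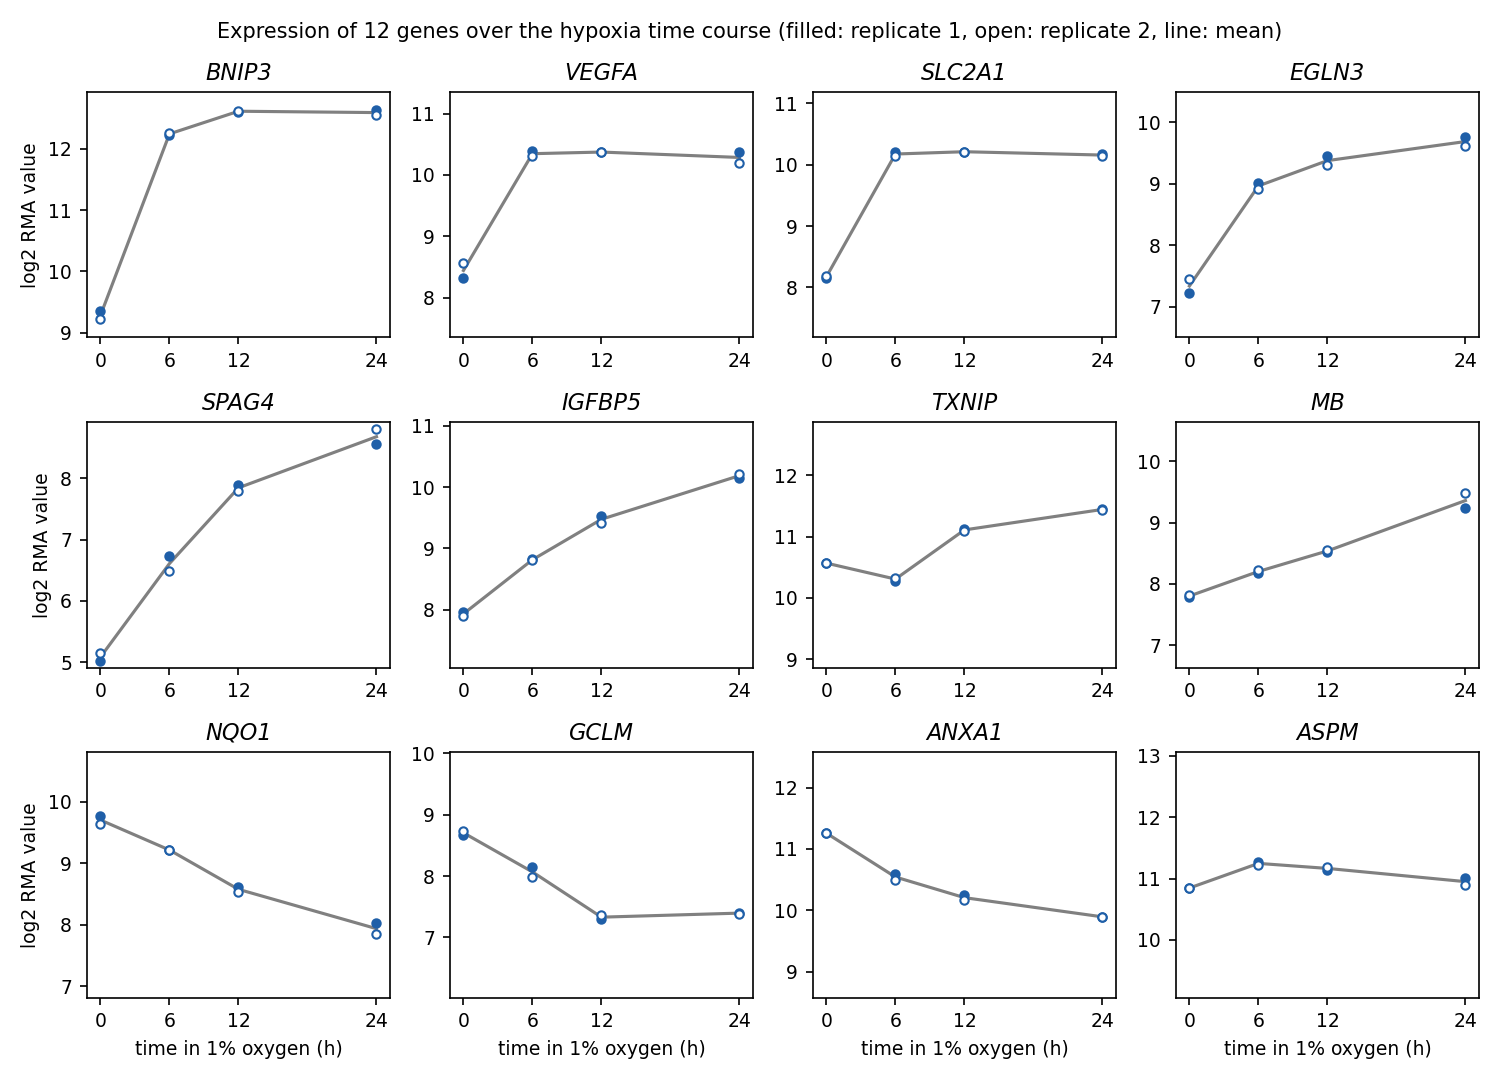
Log2 RMA value of 12 genes on each array against hours in 1% oxygen (filled points replicate 1, open points replicate 2, lines the mean of the 2), each panel spanning the same log2 range. BNIP3 rose by 2.96 by 6 h, SPAG4 reached a rise of 3.59 at 24 h, and NQO1 fell by 1.77 at 24 h.

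After 12 h more genes passed, 853 higher and 1349 lower, with 44 rises and 11 falls of 2-fold or more. BNIP3 rose by 3.33 ± 0.07 (adjusted p = 3.17e-07), SPAG4, a nuclear envelope protein gene, by 2.76 ± 0.11, TMEM45A by 2.66 ± 0.05, PDK1 by 2.32 and DDIT4 by 2.27. The adenylate kinase gene AK4 rose by 2.08, the secreted glycoprotein gene STC1 by 2.07 ± 0.17, and EGLN3, a HIF prolyl hydroxylase gene, by 2.04. The largest falls were in HSPB8 (-1.49 ± 0.11, adjusted p = 0.000275), the glutathione synthesis gene GCLM (-1.38 ± 0.07, adjusted p = 2.56e-05), WDR5B (-1.23) and the quinone reductase gene NQO1 (-1.13 ± 0.08). The next were ARAP2 (-1.09 ± 0.23), ANXA1 (-1.05), HBEGF (-1.04) and STATH (-1.04 ± 0.19). Without 12 h replicate 2 the count of 2202 became 1182, and without 0 h replicate 1 or 2 it became 727 or 655.

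HIF core targets rose in 22 of 27 at 12 h, median 1.31, or 23 adjusted over the list alone (adjusted p = 4.13e-27, 0.0483 with an estimated correlation). Glycolysis genes rose in 20 of 22, the same number adjusted over the list alone (adjusted p = 4.05e-20, 0.0483 with an estimated correlation), although a second probe set of HK2 passed in the opposite direction. Collagen modification and matrix genes rose in 8 of 18, also 8 adjusted over the list alone, with a median of 0.20. LOX, a collagen cross-linking enzyme gene, was at 0.71 (camera adjusted p of the list = 1.02e-06, 0.0483 with an estimated correlation). These were the 3 lists called with both correlations. Mitosis, cholesterol and fatty acid synthesis, and PAX3-FOXO1-associated genes were called higher with the preset correlation only (camera adjusted p = 0.0405, 0.0306 and 0.0104). Demethylase genes rose in 7 of 13, KDM3A by 1.52 and TET1 by 1.38 (adjusted p = 0.000363; adjusted p = 0.159 with an estimated correlation; 7 adjusted over the list alone).

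Further lists were called lower at 12 h with the preset but not with an estimated correlation, and each held members that did not pass. In MYC targets and ribosome biogenesis 10 of 18 fell and 1 rose, or 12 and 3 adjusted over the list alone, led by NIP7 (-0.76), SRM (-0.72), DDX21 (-0.46) and ODC1 (-0.44) (adjusted p = 0.000751; adjusted p = 0.159 with an estimated correlation). Unfolded protein response and ATF4 genes fell in 10 of 23 and rose in 3, or 13 and 3 adjusted over the list alone, with ASNS at -0.95 and TRIB3 at -0.92 (adjusted p = 0.00094; adjusted p = 0.159 with an estimated correlation). Heat shock genes fell in 6 of 12, the same adjusted over the list alone, with STIP1 at -0.35 (adjusted p = 0.00834; adjusted p = 0.159 with an estimated correlation). Mitochondrial import and translation genes fell in 7 of 20, or 8 adjusted over the list alone, with TIMM44 at -0.52 and MRPL12 at -0.41 (adjusted p = 0.00369; adjusted p = 0.159 with an estimated correlation). Immediate early genes fell in 9 of 20, or 11 adjusted over the list alone, with ATF3 at -0.67 (adjusted p = 0.00237; adjusted p = 0.155 with an estimated correlation). NF-kB genes fell in 8 of 16 and rose in 1, or 9 and 1 adjusted over the list alone, with CXCL2 at -0.62 and CCL2 at -0.58 (adjusted p = 0.0154; adjusted p = 0.159 with an estimated correlation).

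The values of the 12 h arrays had a narrower spread, with interquartile ranges over genes of 3.83 and 3.77 against 3.91 to 3.97 on the other arrays. The share of calls that were lower at 12 h was 61.3% as deposited and 54.1% after further quantile normalization. It was 51.5% with each array centred on its median, which leaves the spread as it is. At 24 h these shares were 51.6%, 52.2% and 54.1%.

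After 24 h, 1028 genes were higher and 1095 lower, with 67 rises and 10 falls of 2-fold or more. At an adjusted p under 0.01 in limma the balance turned to 505 higher and 364 lower. SPAG4 showed the largest rise, 12.1-fold (3.59 ± 0.11, adjusted p = 1.88e-06), followed by BNIP3 (3.31 ± 0.07), TMEM45A (2.74), STC1 (2.66 ± 0.17), and PDK1 (2.42). EGLN3 (2.36) and DDIT4 (2.26) followed, with IGFBP5, an insulin-like growth factor binding protein gene (2.25 ± 0.06). The largest falls were in NQO1 (-1.77 ± 0.08, adjusted p = 1.2e-05), HSPB8 (-1.42), ANXA1 (-1.36), GCLM (-1.31), and the glutathione peroxidase gene GPX3 (-1.15 ± 0.13). The next were SLC22A4 (-1.12 ± 0.17), the actin-binding protein gene TAGLN (-1.10) and MAP1A (-1.07). Without 0 h replicate 1 or 2 the count of 2123 became 825 or 791.

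Skeletal muscle differentiation genes rose in 13 of 28 and fell in 3 at 24 h, or 15 and 5 adjusted over the list alone. The troponin genes TNNC1, TNNI1 and TNNC2 rose by 1.17, 0.84 and 0.75 and the myosin light chain gene MYL11 by 0.65 (adjusted p = 0.000452; adjusted p = 0.157 with an estimated correlation). DNA replication genes rose in 8 of 28, the same adjusted over the list alone, with TK1 at 0.45 and MCM6 at 0.34 (adjusted p = 0.00155; adjusted p = 0.125 with an estimated correlation). PAX3-FOXO1-associated genes rose in 8 of 23 and fell in 1, or 11 and 2 adjusted over the list alone, with PIPOX at 1.18, ALK at 0.97 and PDGFRA at 0.95 (adjusted p = 0.00155; adjusted p = 0.157 with an estimated correlation). Cholesterol and fatty acid synthesis genes rose in 6 of 18, also 6 adjusted over the list alone, with INSIG2 at 2.05 and INSIG1 at 0.93 (adjusted p = 0.00155; adjusted p = 0.125 with an estimated correlation).

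HIF core targets rose in 23 of 27 at 24 h, also 23 adjusted over the list alone (median 1.26, adjusted p = 2.57e-29; adjusted p = 0.0588 with an estimated correlation). Glycolysis genes rose in 19 of 22, or 20 adjusted over the list alone (median 0.79, camera adjusted p = 1.7e-22, 0.0588 with an estimated correlation). Collagen modification and matrix genes rose in 7 of 18 and fell in 0, the same adjusted over the list alone. Their median was 0.16 (camera adjusted p = 9.51e-06, 0.0642 with an estimated correlation). Among them were the enzyme genes P4HA1 (1.58) and PLOD1 (0.95). The collagen genes COL1A1, COL1A2 and COL3A1, also in the fibroblast list, were not called higher. Demethylase genes rose in 6 of 13, or 7 adjusted over the list alone (adjusted p = 0.00106; adjusted p = 0.157 with an estimated correlation). MYC targets and ribosome biogenesis genes fell in 9 of 18 and rose in 2, or 11 and 2 adjusted over the list alone, with DDX21, ODC1 and SRM each at -0.51 (adjusted p = 0.00139; adjusted p = 0.157 with an estimated correlation). Heat shock genes fell in 6 of 12, the same adjusted over the list alone, among them HSPH1 at -0.37 (adjusted p = 0.00797; adjusted p = 0.157 with an estimated correlation). Unfolded protein response and ATF4 genes fell in 9 of 23 and rose in 4, the same adjusted over the list alone, with ASNS at -1.05 and ATF4 at -0.77 (adjusted p = 0.0158; adjusted p = 0.191 with an estimated correlation). NF-kB, immediate early and mitochondrial import genes were also called lower at 24 h with the preset correlation (camera adjusted p = 0.021, 0.03 and 0.00968). No list was called at 24 h with an estimated correlation, a form whose p-values rest on 4 degrees of freedom.

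**Figure D4:**
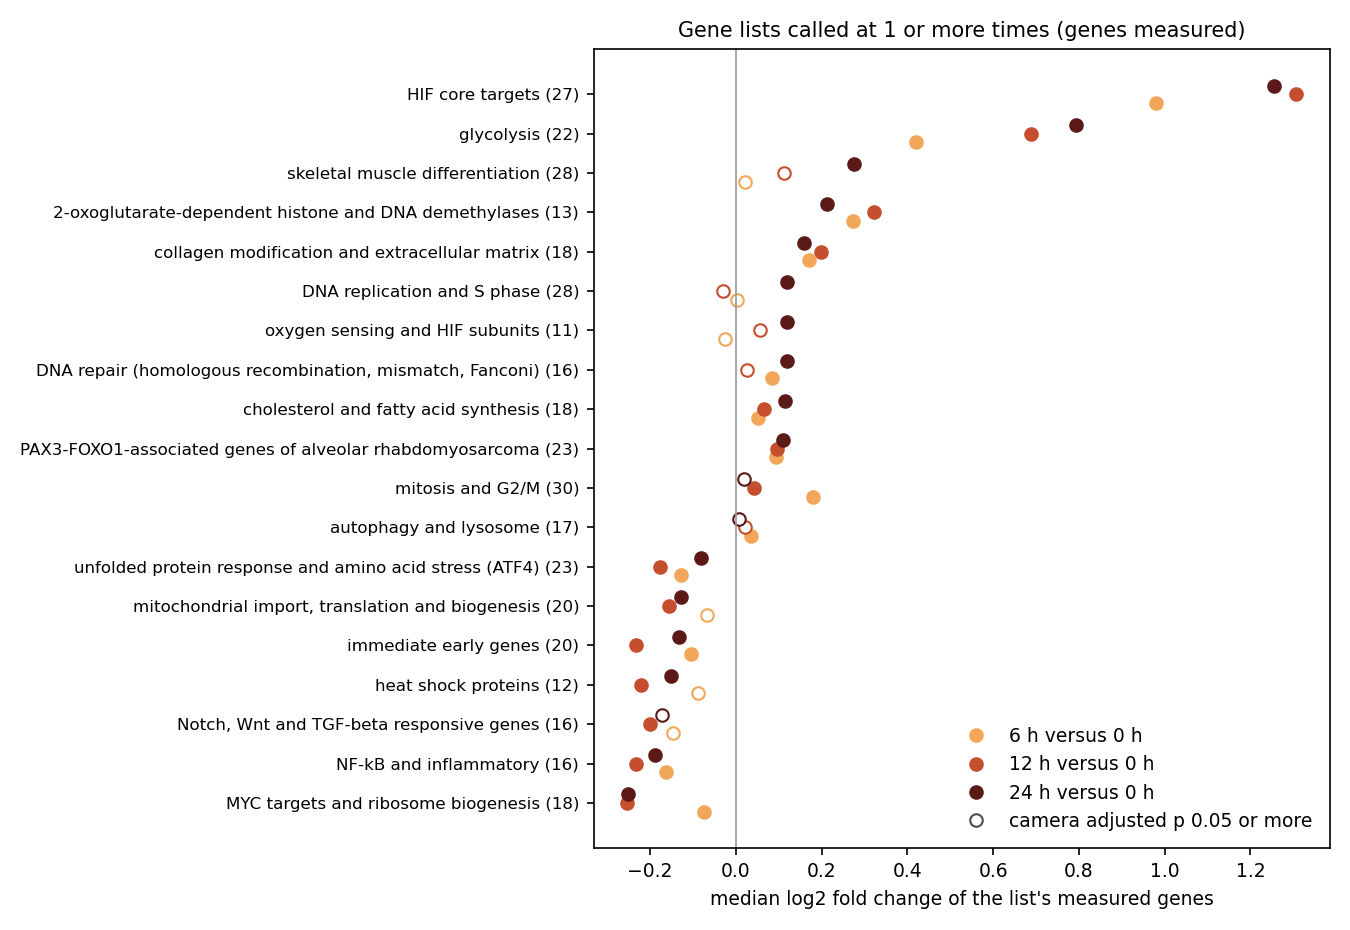
Median log2 fold change against 0 h of each gene list called at 6, 12 or 24 h, with the number of measured genes in brackets; filled points passed camera at the preset correlation and open points did not. HIF core targets lay at 0.98, 1.31 and 1.26 and MYC targets and ribosome biogenesis reached -0.25 at 12 and 24 h.

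Among genes of the HIF subunits, HIF1A was at -0.02, -0.09 and -0.11 and ARNT at -0.04, 0.06 and 0.12 at 6, 12 and 24 h, none past the threshold, although another probe set of ARNT passed in the opposite direction at 24 h. EPAS1 fell by 0.38, 0.44 and 0.30 (adjusted p = 0.0238, 0.00479 and 0.019). NDRG1 rose by 0.59, 1.00 and 1.00, LDHA by 0.53, 0.67 and 0.66, BHLHE40 by 1.83, 1.77 and 1.80, and ADM by 0.98, 1.18 and 1.15. Of the myogenic and tumour identity genes, MYOG was at 0.31 (adjusted p = 0.0166) and MYCN at 0.32 (adjusted p = 0.0135) at 24 h, and PAX3 fell by 0.26 (adjusted p = 0.0455), while MYOD1 (-0.14) and FGFR4 (0.11) did not pass. Of the cell cycle genes, CCNG2 rose by 0.71, 0.72 and 0.66, and CDKN1A fell by 0.45 at 6 h and 0.41 at 12 h and was at -0.19 at 24 h (adjusted p = 0.064). MKI67 rose by 0.29 at 6 h and 0.23 at 12 h and was at 0.13 at 24 h (adjusted p = 0.129). CDKN1B did not pass at any of these times (0.36, 0.17 and 0.06).

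Between hypoxic times few genes passed from 6 to 12 h (17 higher, 7 lower) and from 12 to 24 h (22 higher, 7 lower). From 6 to 12 h SPAG4 rose by 1.23 ± 0.11 (adjusted p = 0.0166), TXNIP, an inhibitor of glucose uptake, by 0.80, IGFBP5 by 0.66, PFKP by 0.63 and RAB26 by 0.61. GCLM (-0.74), NQO1 (-0.64), ADGRG6 (-0.62), EMP1 (-0.58) and UCP2 (-0.54) fell. From 12 to 24 h SPAG4 rose by 0.83, the myoglobin gene MB by 0.82, IQGAP2 by 0.79, IGFBP5 by 0.71 and MYL11 by 0.65. NQO1 (-0.64), RUNX1-IT1 (-0.59), ANKRD36B (-0.59), GPRASP1 (-0.57) and SPDYE2 (-0.55) fell. DNA replication genes rose as a group from 12 to 24 h, median 0.14, with 0 of 28 passing over all genes and 8 adjusted over the list alone (adjusted p = 5.97e-08; adjusted p = 0.0792 with an estimated correlation). In fits of only the groups compared both steps gave 0 genes with limma, against 2631 and 2079 at an unadjusted p under 0.05 in the fit of all arrays. Without 12 h replicate 1 they gave 522 and 139, without 12 h replicate 2 they gave 7 and 0, and without any other array 0 or 1. The balance from 6 to 12 h turned to 200 higher and 554 lower genes with an intensity trend in the variance, 91 and 144 without the dimmest 25% of genes, and 209 and 656 without the dimmer 50%.

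From 6 to 24 h, 221 genes were higher and 112 lower. SPAG4 rose by 2.07 ± 0.11 (adjusted p = 0.000359), IGFBP5 by 1.37, STC1 by 1.29, the integrin gene ITGB2 by 1.17 and MB by 1.16. NQO1 (-1.28), GPX3 (-0.90), NIBAN1 (-0.85), HSPB8 (-0.76) and SUSD5 (-0.72) fell. Glycolysis genes rose in 12 of 22, or 14 adjusted over the list alone, with PFKP at 0.81 and ALDOC at 0.68 (adjusted p = 5.97e-10, 0.162 with an estimated correlation). PFKP had already passed at 6 h against 0 h, while ALDOC and several others of these genes had not. Muscle genes rose in 8 of 28, or 10 higher and 3 lower adjusted over the list alone, with TNNC2 at 0.81 and MYL11 at 0.76 (adjusted p = 0.000206; adjusted p = 0.222 with an estimated correlation). Mitosis genes fell as a group, with ASPM (-0.30) the 1 of 30 past the threshold and 9 adjusted over the list alone (adjusted p = 2.37e-06; adjusted p = 0.14 with an estimated correlation). Without 6 h replicate 1 or 2 the count was 18 or 44, without 24 h replicate 1 or 2 it was 66 or 59, and without either 0 h array it was 123. With an intensity trend 526 genes were higher and 513 lower, and without the dimmer 50% of genes 508 and 529.

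Of the 277 genes higher at 6 h, 250 were also called higher at 24 h, and of the 146 lower genes 134 were also called lower. Of the 277 genes higher at 6 h, 59 rose further by 24 h, 4 came back and 214 did not pass the test between these times. Of the 146 lower genes, 21 fell further, 3 came back and 122 did not pass. The 80 genes that went further became 20 and 21 without 0 h replicate 1 or 2, 5 and 14 without 6 h replicate 1 or 2, and 29 and 30 without 24 h replicate 1 or 2. The 7 that came back became 1 without either 0 h array, 0 without either 6 h array (limma), 4 without either 12 h array, and 3 and 2 without 24 h replicate 1 or 2; at an unadjusted p under 0.05, 2277 genes differed between 6 and 24 h. The genes that came back, named after their values were seen, were ASPM, CSTF3, PTCH1 and SLC6A15, which had risen, and DUSP6, S100A2 and TXNIP, which had fallen. TXNIP went from -0.26 at 6 h to 0.88 at 24 h (24 h minus 6 h 1.14 ± 0.05, adjusted p = 0.000229). The 250 and 134 genes called at both times compare with 23.8 and 13.4 for independent lists. Simulated unchanged groups sharing the 0 h arrays gave 0 and 0.01. Without real changes almost no gene is called, so these values are no baseline for the counts. The correlation of the changes across genes was 0.77 (0.50 simulated) and their covariance 0.0322 (0.00518 simulated). The 2 control arrays were not split, since each part would hold 1 array. Part of the excess over independent lists and part of the correlation may therefore come from the shared controls.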

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

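The comparison of 24 h with 6 h was planned before the data were examined. The tests of explanations for the control probe sets in this part were chosen only after the result was seen.

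The responses at 24 h and 6 h differed for 333 genes by the limma test of 24 h against 6 h, in which the 0 h arrays cancel. Without 6 h replicate 1 or 2 this count was 18 or 44, without 24 h replicate 1 or 2 it was 66 or 59, and without either 0 h array it was 123. The list medians for 24 h minus 6 h were 0.37 for glycolysis, 0.20 for skeletal muscle differentiation, 0.17 for HIF core targets, 0.10 for DNA replication and 0.10 for cholesterol and fatty acid synthesis. They were -0.0591 for mitochondrial import and translation, -0.0825 for oxidative phosphorylation, -0.10 for MYC targets and ribosome biogenesis, -0.13 for heat shock genes and -0.16 for mitosis genes. None of these lists was called with an estimated correlation (lowest adjusted p = 0.14 with an estimated correlation).

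Among single genes the response was larger at 24 h for SPAG4 (2.07), IGFBP5 (1.37), STC1 (1.29), ITGB2 (1.17), MB (1.16), EGLN3 (0.72), NDRG1 (0.42), PDK1 (0.38) and BNIP3 (0.35). NQO1 (-1.28), GPX3 (-0.90), NIBAN1 (-0.85), HSPB8 (-0.76) and SUSD5 (-0.72) were lower at 24 h than at 6 h.

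Signals outside the gene comparisons also differed from 0 h. The poly-A control probe sets were higher by 0.47 at 6 h, 0.43 at 12 h and 0.65 at 24 h. The 28S ribosomal RNA probe set was at -1.01 at 24 h and an 18S probe set at 0.03. Among 3151 probe sets without a single gene name, 265 were called at 24 h, 138 higher and 127 lower.

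A difference in brightness or hybridisation would raise hybridisation controls of like brightness as much as the poly-A controls, but their difference was larger on every hypoxia array than on both 0 h arrays, by at least 0.142 against a largest replicate difference of 0.0793. A single different amount of control RNA in the 0 h samples would leave the hypoxic times alike, but they spanned 0.233, more than the rise of 0.162 from 0 to 6 h, a small margin that leaves amounts differing from time to time open. Less polyadenylated RNA per total RNA in hypoxic cells is a candidate explanation, and all 24 poly-A probe sets were higher at each time. These are repeat readings of a few added transcripts, not 24 separate observations. Amounts of control RNA differing from time to time would give the same, so these explanations cannot be told apart here. With each array scaled to its poly-A controls, the median gene was at -0.48, -0.42 and -0.66 at 6, 12 and 24 h, and 66, 129 and 110 genes were higher against 11355, 10155 and 11505 lower. This scaling overstates the shift specific to the poly-A controls, since hybridisation controls of like brightness also rose by 0.29, 0.23 and 0.25, which leaves 0.16, 0.19 and 0.39.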

How the results depend on the processing

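Leaving out both 12 h arrays and crossing the replicate numbers at 12 h were chosen only after the result was seen; the other settings were planned. Over 192 list results, 3802 outcomes kept direction and side of the threshold, 165 became weaker, 112 stronger and 1 reversed; over 625 results of named genes these numbers were 11092, 1179, 359 and 1. With 2 arrays per time, the number of arrays and, for dim genes, the signal over background limit what can be called. Causes were not tested unless stated.

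The reversed results were the skeletal muscle list from 12 to 24 h without the dimmer 50% of genes, where camera turned (median 0.0128), and H2AX at 12 h, at 0.0565 with the mean of all its probe sets, a second probe set of which passed in the opposite direction.

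Counts below are in the order 6 h, 12 h and 24 h against 0 h, then 12 against 6 h, 24 against 12 h and 24 against 6 h. At an adjusted p under 0.01 they were 150, 802, 869, 1, 0 and 52 with limma (2079 for the 0 at an unadjusted p under 0.05), 518 by the F-test, 18 genes further, 0 back and 142 called at both 6 and 24 h, and 9, 5 and 6 lists were called for 12 h against 0 h, 12 against 6 h and 24 against 6 h. At 0.10 there were 843 genes at 6 h, 331, 150 and 717 between hypoxic times, 3139 by the F-test, 155 further, 25 back, and 14 lists for 12 against 6 h. A stricter or looser threshold explains these by construction.

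An intensity trend in the variance gave 1206 genes at 6 h, 754, 404 and 1039 between hypoxic times, 3333 by the F-test, 258 further and 69 back. The robust form gave 1173, 710, 374, 999, 3314, 247 and 61. Without the dimmest 25% of genes the counts were 776 at 6 h, 235, 127 and 623 between hypoxic times, 145 further and 20 back. Without the dimmer 50% they were 1323, 865, 465, 1037, 282 and 84, with 3043 by the F-test and 5 lists for 24 against 6 h. Testing all probe sets gave 7 for 24 against 12 h.

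Fits of only the groups compared gave 0, 0 and 184 genes between hypoxic times with limma (2631 and 2079 at an unadjusted p under 0.05 in the fit of all arrays) and 14 lists for 12 against 6 h; fewer arrays enter them. A further quantile normalization gave 48 genes and 5 lists for 12 against 6 h. Centring arrays moved the share of lower calls from 24.1% to 35.0% for 24 against 12 h. Neither centring nor the further quantile normalization moved the median of all genes by over 0.1, unlike scaling to the poly-A controls, given with those controls. With an estimated correlation 4, 3, 0, 0, 0 and 0 lists were called; fry called 22 for 12 h against 0 h, 15 for 12 against 6 h and 7 for 24 against 12 h.

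Replicate numbers are shared labels only: deviations of same-numbered arrays correlated at -0.113 to 0.0855. With a replicate block there were 272 genes at 6 h, 8, 0 and 157 between hypoxic times, 44 further and 2 back (2079 for the 0 at an unadjusted p under 0.05 in the limma fit without it); no other count moved by over 1.5 times. With the block crossed at 12 h there were 1986, 8 and 0 genes for 12 h against 0 h, 12 against 6 h and 24 against 12 h. Without both 12 h arrays there were 418, 2169 and 359 genes for 6 h and 24 h against 0 h and 24 against 6 h, and 4 back.

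Leaving out 1 array gave 90 to 508 genes at 6 h (92 and 111 without 0 h replicate 1 or 2, 90 and 131 without 6 h replicate 1 or 2), 655 to 2507 at 12 h (727 and 655 without 0 h, 1182 without 12 h replicate 2) and 791 to 2169 at 24 h (825 and 791 without 0 h). It gave 0 to 522 for 12 against 6 h and 0 to 139 for 24 against 12 h, 522 and 139 without 12 h replicate 1, 7 and 0 without 12 h replicate 2, and 0 or 1 without any other. For 24 against 6 h it gave 18 to 359 (18 and 44 without 6 h, 66 and 59 without 24 h, 123 without either 0 h array), for the F-test 374 to 2099 (397 and 374 without 0 h, 943 and 1063 without 6 h), 5 to 77 further and 0 to 4 back. Lists called ranged over 12 to 16, 12 to 15, 15 to 17, 6 to 13, 2 to 5 (5 without 24 h replicate 1) and 6 to 11 (6 without 24 h replicate 1). The lone array left is assumed to vary like the other groups.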

Other observations

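The tests of explanations in this part, of the lower calls at 12 h and of the NRF2-associated genes, were chosen only after the result was seen; the gene lists of the next 2 paragraphs were planned.

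Several lists had smaller or mixed changes. DNA repair genes rose in 4 of 16 at 24 h, or 6 adjusted over the list alone, with XRCC2 at 0.61, FANCI at 0.50 and BARD1 at 0.45 (camera adjusted p = 0.00154; adjusted p = 0.191 with an estimated correlation). In oxygen sensing 3 of 11 rose and 1 fell at 24 h, or 4 and 1 adjusted over the list alone, with the prolyl hydroxylase genes EGLN3 at 2.36 and EGLN1 at 1.48 (adjusted p = 0.0316; adjusted p = 0.157 with an estimated correlation). The autophagy list was called at 6 h, 3 of 17 higher and 1 lower, or 4 and 2 adjusted over the list alone, led by the mitophagy receptor genes BNIP3 (2.96) and BNIP3L (1.16), while SQSTM1 fell by 0.40 (adjusted p = 0.0292, 0.156 with an estimated correlation). BNIP3 and BNIP3L are also in the list of HIF core targets, and the median of the autophagy list was 0.04. Notch, Wnt and TGF-beta responsive genes fell in 7 of 16 and rose in 1 at 12 h, or 8 and 1 adjusted over the list alone, with ID2 at -0.66, SMAD7 at -0.59 and ID1 at -0.52 (adjusted p = 0.0405; adjusted p = 0.208 with an estimated correlation). The interferon list was not called at 24 h (adjusted p = 0.355), although IFITM1 rose by 0.80 and ISG20 by 0.60; its median was -0.02 and its mean 0.08. Oxidative phosphorylation genes fell in 6 of 28 and rose in 1 at 24 h, the same adjusted over the list alone, and the list was not called (adjusted p = 0.118). Among splicing genes the kinase gene CLK3 rose by 0.56 at 24 h, with no call of the list (camera adjusted p = 0.88). Angiogenic factors were not called by camera at 6, 12 or 24 h (adjusted p = 0.577, 0.182 and 0.346). Of 16 genes, 3, 2 and 3 rose and 0, 2 and 2 fell, with list medians of -0.05, 0.10 and 0.05. The fry test called this list higher at each of these times (adjusted p = 0.00343, 0.0014 and 0.00188).

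Of the markers of other cell types, the epithelial list was called from 6 to 12 h with 0 of 12 genes past the threshold in limma, also 0 adjusted over the list alone (median 0.15, adjusted p = 0.0226; adjusted p = 0.236 with an estimated correlation), a comparison with 2631 genes at an unadjusted p under 0.05. With camera the blood, endothelial, fibroblast and neural lists were called in none of the 6 comparisons. The fry test called the neural list higher at 12 h (adjusted p = 0.0122), at 24 h (0.00571), from 6 to 12 h (0.0241) and from 6 to 24 h (0.0115), the blood list higher from 6 to 12 h (0.0241) and the endothelial list higher at 24 h (0.0257). From 6 to 12 h the medians of the blood, endothelial, fibroblast and neural lists were also above the zero line, at 0.19, 0.07, 0.12 and 0.12. From 12 to 24 h the epithelial and blood medians were -0.13 and -0.09. Dim minus bright genes lay at 0.103 and 0.115 on the 12 h arrays, relative to 0 h. The brightness of these marker genes was not tested. The calls that involve 12 h can therefore not be told apart from this shift of dim genes. The neural genes DCX and NCAM1 rose by 0.59 and 0.52 at 24 h. The reference gene list was not called by camera either (adjusted p = 0.867 at 24 h). Within it HPRT1 rose by 0.58 and ACTB fell by 0.38 at 24 h, in the same direction after a further quantile normalization and with arrays centred.

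At 12 h 61.3% of calls were lower, against 51.6% at 24 h. A narrower spread of values on the 12 h arrays is a candidate explanation for the excess, and after a further quantile normalization the shares were 54.1% and 52.2%. With each array centred on its median, which leaves the spread as it is, they were 51.5% and 54.1%. The excess thus also ended with centring, without any change of spread. It remained under other settings. At an adjusted p under 0.01 in limma the shares at 12 h and 24 h were 55.9% and 41.9%. Without the dimmer 50% of genes they were 66.4% and 55.1%. With the mean of all probe sets of a gene they were 63.9% and 53.2%. Without 12 h replicate 1 or 2, which leaves the spread of the array kept as it is, the share at 12 h was 53.5% or 56.2% against 51.7% at 24 h, so the narrower spread stays open. Both shares were below 61.3%, so they do not single out replicate 2 of 12 h. Each rests on 1 array at 12 h, so they cannot decide whether replicate 2 alone gave the excess. Dim minus bright genes lay at 0.103 on replicate 1 and 0.115 on replicate 2, against -0.04 to 0.03 on the 6 h and 24 h arrays. The shift between dim and bright genes was therefore not confined to replicate 2. Whether the narrower spread is technical or comes from the cells was not tested.

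NQO1 and GCLM at 24 h and HMOX1 at 6 h, targets of the oxidative stress regulator NRF2, were among the largest falls, which prompted the hypothesis that NRF2-associated genes fell as a group at 24 h. In 23 measured NRF2-associated genes other than these and SLC7A11, whose value had also been seen, it was not borne out: their median of -0.08 lay at percentile 5.64 of 10000 random lists of like brightness, a narrow miss of the lowest 5% the hypothesis needed, and camera with an estimated correlation gave 0.213. At 12 h, for which no test had been set, the median was -0.19 and the percentile 0.01, and camera gave 0.0173, or 0.118 with an estimated correlation. At 24 h 6 of the 23 genes were lower and 2 higher past the threshold, and with 0 arrays of cells kept in normal oxygen for 6 h or longer, time in culture cannot be told apart from low oxygen.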
